A study of Danio rerio with 8 samples.

How the data were processed

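RNA was measured by bulk RNA sequencing in ventricles of adult zebrafish, the F1 offspring of uninjured mothers and of fathers that were either uninjured or had a cryoinjury of the heart (a freeze wound of the ventricle) and were crossed 7 days afterwards. Per the labels' protocols, the atrium and the bulbus arteriosus were removed, the ventricle was cut open to let red blood cells out, and each library pooled 4 sibling fish. There were 4 libraries per group, which the labels call biological replicates. The labels used here do not state whether the pools of a group had different fathers, so p-values measure the spread between pools. Libraries were made from 1 ng of RNA with the Ovation Single Cell kit and 2 rounds of amplification, and were read as single reads of 60 bases on an Illumina HiSeq2500, per the labels' protocols.

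The deposited table holds raw counts of reads per gene, whole numbers that the authors did not normalise. Per the file headers, the authors counted reads with featureCounts 2.0.3 against the Ensembl annotation of GRCz11, release 111, with strand option 0, and without counting multi-mapping reads or reads that overlap several genes. Per the submitters' processing notes, reads were checked with FastQC 0.11.9 and MultiQC 1.12, aligned with STAR 2.7.10a, and analysed in R 4.4.0 with DESeq2 1.44.0. Because strand was not used, reads from the opposite strand of a gene count toward it, while reads that lie where annotated genes overlap were left out. Reads that map to several copies were not counted, so values of multigene families (ifi27, herc56, mx, ftr, haemoglobin, MHC class I and the immunoproteasome genes) are uncertain for single members. The counts were made from amplified reads without molecular identifiers, so they are not counts of independent molecules.

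The table has 32520 genes. A table of gene names gave a symbol to 29201 of them (89.8%), and to 96.8% of the tested genes. Many symbols in that table are written in capitals after the human gene, and some stand for several zebrafish genes; SOCS3, MYOM1, SLC2A1 and EPAS1 are such names, and the chromosome is given where a value of one is printed. Coordinates are those of the counts table on GRCz11.

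The main comparison, injured against uninjured father, used the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr with its minimum count of 10, robust estimation and Benjamini-Hochberg adjustment at 0.05; 13604 genes were tested. Log2 folds are those of edgeR. Their standard errors (SE) were derived from the test, as the absolute log2 fold over the square root of its F statistic, so they add nothing to its p. Levels are CPM (counts of a gene over the TMM-scaled total of its library, times 1e6), as mean ± SD. On simulated data drawn for this comparison with 13279 genes run and 200 of them changed, in 5 simulations, the same code recovered 24.6% of the genes at a fold of 2 and 84.4% of those at a fold of 4, with 5.45% of calls false. A list raised by a fold of 1.5 was called in 5 of 5 simulations. The simulated genes were drawn independently of each other, so the simulations do not test list calls where the members of a list are correlated.

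Before the data were examined, 35 gene lists (cell types, pathways and complexes that fit the heart, the injury and the dissection) were fixed, and 33 had at least 5 tested members. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and the fry test were alternatives. With the preset correlation camera also called up to 12 lists in splits of the libraries that mix the groups. Its adjusted p-values alone therefore do not mark the father's group. A list score is the mean log2 CPM of the members in a library. Scores and shares of counts were compared with exact two-sided permutation tests over the 70 assignments of 8 libraries to 2 groups of 4, whose smallest p is 0.0286. List members were matched by symbol and synonym; 2 matches took a synonym of another gene (polr1g in the lymphocyte list and PRPF38A in the nerve list).

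The rule for named genes was also fixed beforehand. It took up to 10 genes per direction past the threshold with a mean log2 CPM of at least 1, and filled each direction to 10 with the genes of smallest p at any mean; symbols that are clone names were skipped. None passed, so all came by their p. It added up to 4 members with the smallest p from each list described, and hbaa1, MYL7, nppa and nppb as reference genes; hbba1, also in the rule, matched no tested gene. Of the list members that the rule took, the text prints only some, picked after their values were seen. Apart from that choice, 1 gene is not reported here; it stays in the tests of all genes and of the lists. Any other named gene is said to have been chosen after its values were seen.

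Alternatives were other scalings, filters, tools (DESeq2 1.42.0, limma voom), thresholds, the haemoglobin share or 1 surrogate variable (sva 3.50.0) as a covariate, a gene length offset, the number in the title as a block, and each library left out. The mean haemoglobin share differed between the groups, so a fit with it can take up part of their difference. The genome sequence was not used here, so GC content was not tested. Totals ran from 8441014 to 16290169 counts per library, so 1 CPM stood for 9.12 to 17.2 counts, and 3 counts for 0.175 to 0.329 CPM. Those limits cover counting error only.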

Results

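The series asks whether a heart injury of the father alters gene expression in the unperturbed adult heart of the offspring. Ventricles of offspring of uninjured fathers gave 4 libraries, numbered 1, 3, 4 and 5 in the labels, with 13465112, 12450251, 14736121 and 13769659 counts. Ventricles of offspring of injured fathers, crossed 7 days after cryoinjury, gave 4 libraries, numbered 1, 2, 4 and 7, with 10423400, 8441014, 14478326 and 16290169 counts. Between 18398 and 19179 genes had at least 1 count per library. The 10 most abundant genes took 30.7% ± 1.18 (SD, n = 4) of the counts with uninjured fathers and 30.3% ± 1.72 with injured fathers. Each library was counted as 1 replicate, as the labels have it.

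Antiviral and other immune genes headed the genes that were higher with an injured father. RSAD2 (viperin, an interferon-induced antiviral enzyme; ENSDARG00000004952, GRCz11 chromosome 17, 35357451 to 35361322) was at 29.6 ± 24.6 CPM (SD, n = 4) against 4.45 ± 0.805 CPM with uninjured fathers, a log2 fold of 2.74 (SE 0.47). The chemokine gene cxcl18b (ENSDARG00000075045, chromosome 1, 49222164 to 49225890) was at 30.1 ± 7.32 against 10.3 ± 2.89 CPM, a log2 fold of 1.55 (SE 0.25). The ubiquitin-ligase family gene herc56.4 was at 19.1 ± 14.4 against 2.56 ± 0.767 CPM, and ifi27.3, of an interferon-inducible family, at 24.6 ± 16.2 against 5.39 ± 1.64 CPM. The gene isg15, of a ubiquitin-like modifier, was at 7.99 ± 4.73 against 1.79 ± 0.446 CPM, and parp14rs1 at 40.4 ± 7.86 against 21.0 ± 0.874 CPM. Further genes among the 10 with the smallest p were lgals9l1 of the galectin 9 family (log2 fold 1.53), igldcp (2.17) and helz2a (1.77).

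Genes with lower values were of other kinds. MYLK3, the cardiac myosin light chain kinase (ENSDARG00000076348, chromosome 7, 41821311 to 41858513), was at 323 ± 29.2 CPM (SD, n = 4) with injured fathers against 506 ± 55.6 CPM, a log2 fold of -0.65 (SE 0.15). The transcription factor gene foxo3b (ENSDARG00000042904, chromosome 20, 32286765 to 32332736) was at 92.0 ± 14.2 against 242 ± 125 CPM, a log2 fold of -1.39 (SE 0.30). SLC38A4, an amino acid transporter, was at 72.1 ± 7.53 against 213 ± 120 CPM, and CHD5, a chromatin remodeller, at 12.01 ± 6.17 against 33.9 ± 7.63 CPM. OAT (ornithine aminotransferase) had a log2 fold of -1.07, mid1ip1l -0.93, MAPK4 -1.24, EEPD1 -1.34, pkn3 -1.86 and usp2b -1.56. The uninjured library numbered 4 had the highest level of the 8 in 7 of these 10 genes, among them foxo3b (425 CPM), MYLK3, SLC38A4 and CHD5.

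In each of these genes all 4 libraries of one group lay beyond all 4 of the other, but none passed the edgeR test after adjustment, with the smallest adjusted p at 0.31. Across the 13604 genes tested, edgeR called 0 genes. An unadjusted p under 0.05 was reached by 971, against 680 that chance gives on average, with 499 higher and 472 lower. That excess does not exclude chance, since 8 of the 35 splits of the libraries, the real one included, gave as many such genes. The division into higher and lower was 761 and 267 with library sizes alone as the scaling, and 594 and 369 with upper-quartile factors. It was 523 and 745 without the uninjured library numbered 5, 430 and 305 without the one numbered 4, 319 and 318 without the injured library numbered 4, and 214 and 209 with the haemoglobin share in the model. Limma voom called 0 genes with and without quality weights, and DESeq2 called 57, of which 44 were higher and 13 lower. The groups did not overlap in 354 genes with injured fathers above and 215 below, 4.18% of the tested genes where chance gives 2.86%.

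**Figure D1:**
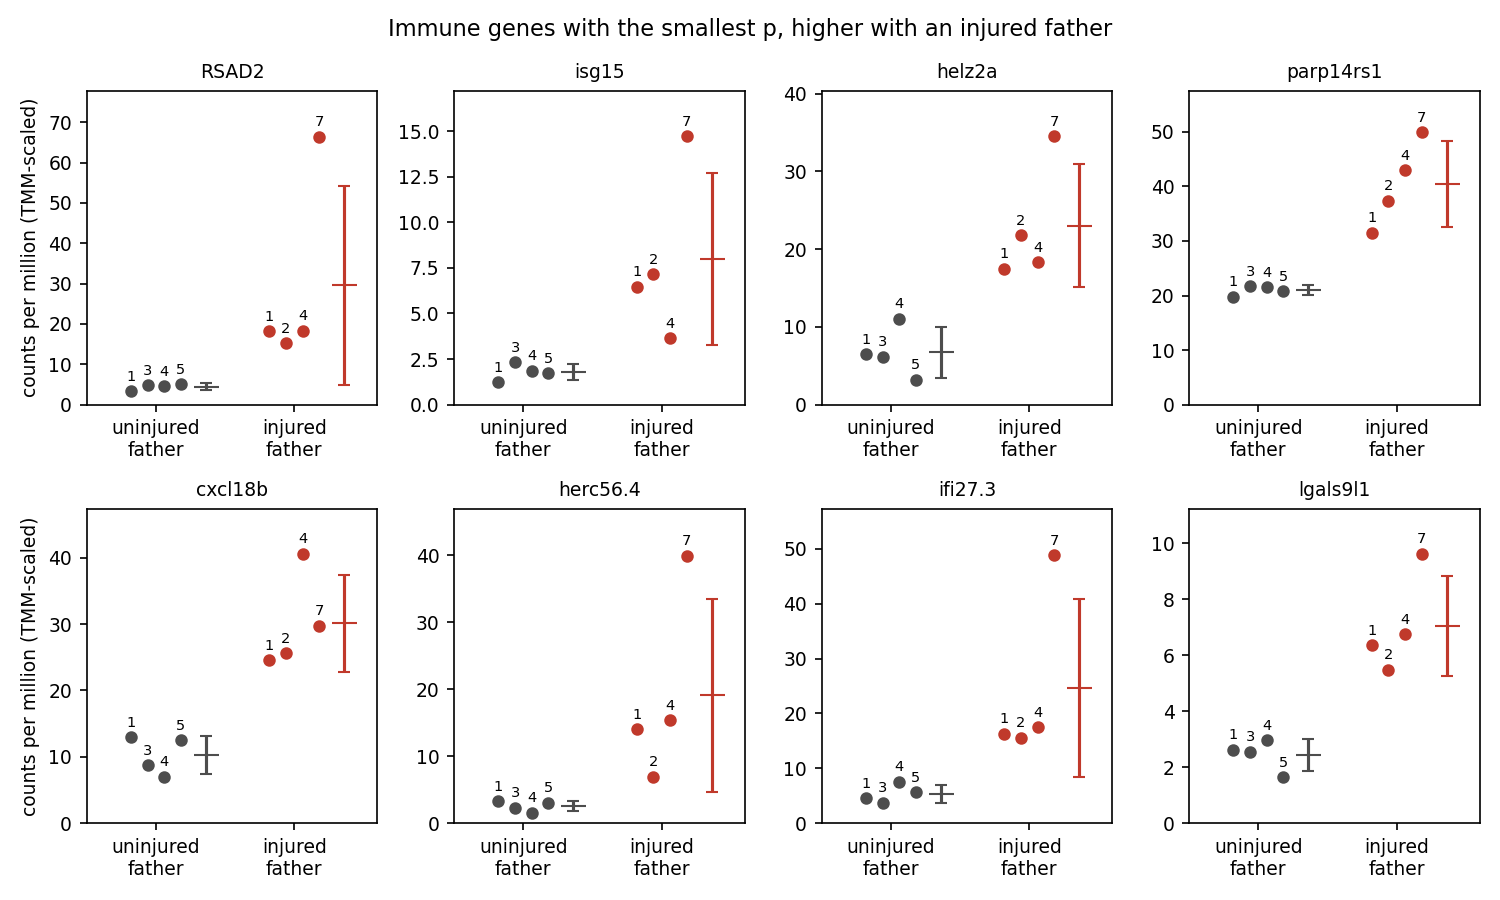
CPM (TMM-scaled, linear axes from 0) of 8 genes in each library; points are libraries with their numbers, the bars beside them mean and SD (n = 4). The injured library numbered 7 has the highest value in all panels but that of cxcl18b, and in each panel the 4 libraries of injured fathers lie above the 4 of uninjured fathers.

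Interferon response genes, the machinery that cells switch on against viruses, were higher as a group with injured fathers. Of the 28 tested members, 26 had a positive log2 fold and 21 of these an unadjusted p under 0.05; the mean log2 fold was 1.14 and the median 0.94. The groups did not overlap in 17 members, where chance gives 2.86% of genes. Besides RSAD2, isg15 and parp14rs1, members with large differences were SOCS1, a feedback inhibitor of cytokine signalling (log2 fold 1.91), CMPK2 (1.65), the RNA sensor gene DHX58 (1.42) and the antiviral GTPase genes mxa (2.18) and mxe (1.45); these 5 were chosen after their values were seen. SAMHD1 (-0.15), IFIH1 (0.08), adar (0.07) and ifit11 (-0.03), likewise chosen, were close to 0. Camera gave the list an adjusted p of 5.1e-20 with the preset correlation, and an adjusted p = 0.27 with an estimated correlation. With edgeR p-values adjusted over the list alone, 20 members passed, all of them higher; over all genes tested 0 passed. DESeq2 called 10 of the 28 members over all genes, and ifit10, a list member that the edgeR filter left out, all of them higher.

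The list score was 3.40 ± 0.433 with injured fathers and 2.38 ± 0.190 with uninjured fathers (SD, n = 4), and every library of injured fathers lay above every library of uninjured fathers. The exact permutation p was 0.029, the smallest the design allows, and 0.28 after adjustment over the 33 lists. The injured library numbered 7 had the highest score (4.04), and 20 of the 28 members were highest there; without it the mean log2 fold of the list was 0.82.

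Inflammatory cytokine and NF-kB target genes were also higher as a group, with 18 of 25 tested members positive, 8 of them at an unadjusted p under 0.05, and a mean log2 fold of 0.42. Alongside cxcl18b, the cytokine gene il34 was at 8.998 ± 1.78 against 5.56 ± 0.721 CPM (SD, n = 4) and the TNF receptor gene tnfrsf1b at 9.34 ± 0.957 against 6.0 ± 1.17 CPM. PTGS2, the prostaglandin-forming cyclooxygenase, was at 9.35 ± 9.74 against 1.89 ± 1.31 CPM, with 23.9 CPM in the injured library numbered 4; without that library the mean log2 fold of the list was 0.22. Camera gave an adjusted p of 0.00056, and an adjusted p = 0.27 with an estimated correlation; 1 member, cxcl18b, passed with p-values adjusted over the list alone. The score of each injured-father library exceeded that of each uninjured-father library, with an exact permutation p of 0.029 and an adjusted p of 0.28. Over the 8 libraries this score followed the first principal component of all genes (r = 0.81, against 0.25 for the interferon score), which did not separate the groups. The call ended with the haemoglobin share in the model (mean log2 fold 0.14), and the mean was 0.27 with 1 surrogate variable and 0.83 over 47 members without the low-count filter.

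Antigen presentation genes followed the same direction: all 23 tested members of the MHC list had a positive log2 fold, with a mean of 0.55. The class I transactivator nlrc5 was at 23.2 ± 2.90 against 14.2 ± 2.53 CPM (SD, n = 4), the peptide-loading gene tapbp.2 at 5.72 ± 0.773 against 3.60 ± 0.603 CPM, and the immunoproteasome gene PSMB8 at 18.5 ± 11.4 against 9.20 ± 2.66 CPM. Of the 23 members, 9 lie on chromosome 19, with a mean log2 fold of 0.80 there and 0.40 for the 14 elsewhere. Camera gave an adjusted p of 4.4e-07, and an adjusted p = 0.34 with an estimated correlation. With edgeR p-values adjusted over the list alone 0 members passed, and 7 had an unadjusted p under 0.05, 6 of them on chromosome 19 and 1 elsewhere. Without the injured library numbered 7 the mean log2 fold was 0.30.

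**Figure D2:**
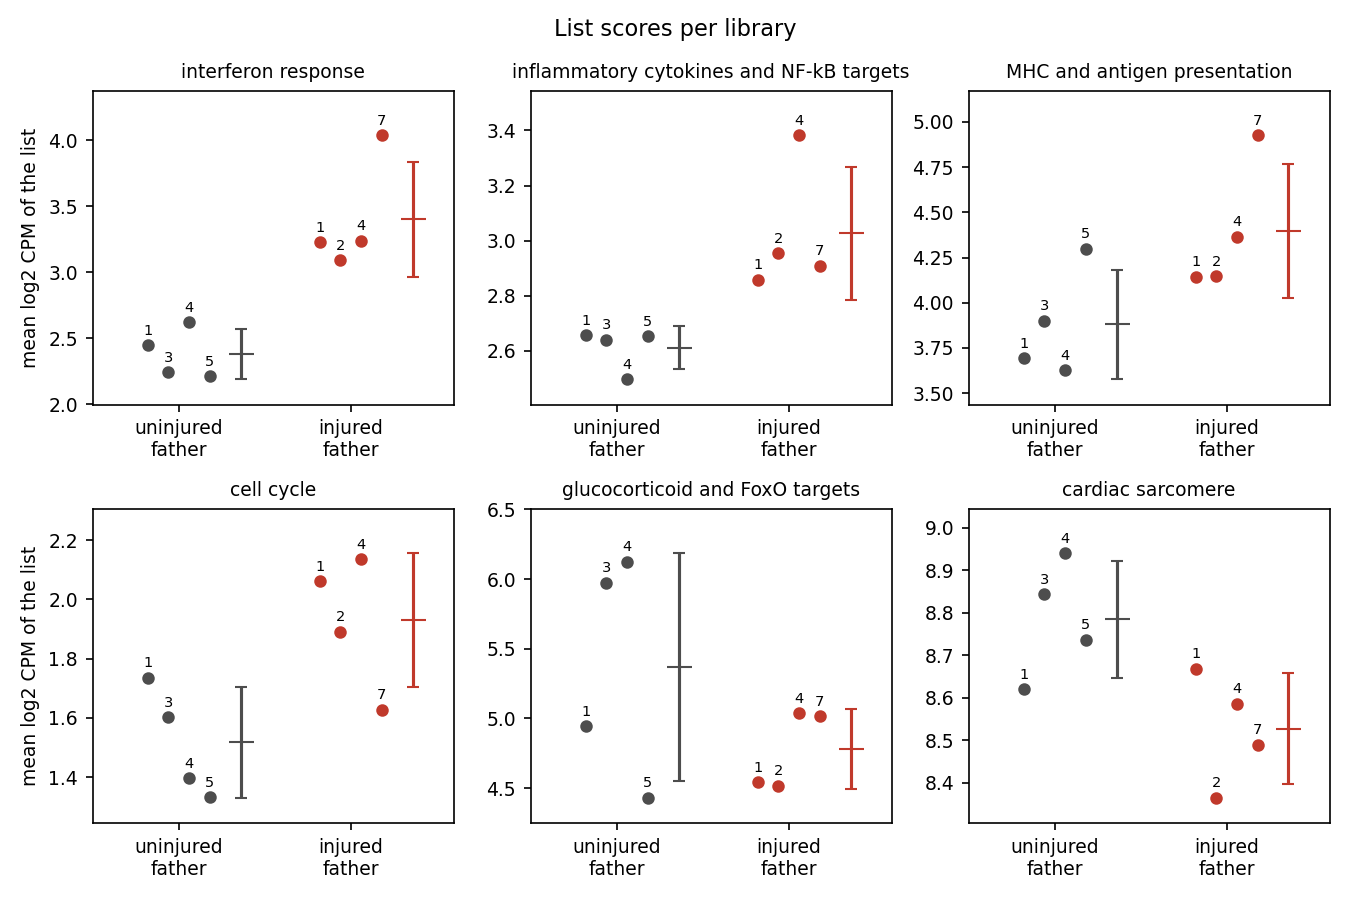
Score (mean log2 CPM of the tested members) of 6 gene lists in each library, with library numbers at the points and bars for mean and SD (n = 4); the axes do not start at 0. The interferon and the inflammatory scores of the 2 groups do not overlap, while the other 4 do.

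Genes of the glucocorticoid and FoxO target list, which respond to stress hormones and fasting, were lower as a group with injured fathers. Of 25 tested members, 24 had a negative log2 fold and 8 an unadjusted p under 0.05, with a mean log2 fold of -0.70. With foxo3b, these included the stress-response gene SESN1 at 108 ± 27.5 against 194 ± 67.9 CPM (SD, n = 4), the repressor gene BCL6 at 0.959 ± 0.404 against 2.33 ± 1.07 CPM, and the hypoxia-inducible factor gene hif1al at 67.3 ± 21.9 against 165 ± 109 CPM. Camera gave an adjusted p of 2.6e-05, and an adjusted p = 0.42 with an estimated correlation; 1 member, foxo3b, passed with p-values adjusted over the list alone. List scores overlapped, at 4.78 ± 0.286 against 5.37 ± 0.815, with an exact permutation p of 0.34. The mean log2 fold was -0.44 without the uninjured library numbered 4 and with 1 surrogate variable, and -1.12 with the haemoglobin share in the model.

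Proliferation genes were slightly higher. Of 32 tested cell cycle genes, 30 had a positive log2 fold, with a mean of 0.42 and 4 at an unadjusted p under 0.05: TOP2A, a topoisomerase of dividing cells, was at 6.66 ± 1.77 against 3.14 ± 1.197 CPM (SD, n = 4), the kinetochore gene cenpe at 1.41 ± 0.591 against 0.454 ± 0.361 CPM, and the nucleotide synthesis genes TYMS and RRM2 had log2 folds of 0.75 and 0.76. Camera gave an adjusted p of 8.0e-06, and an adjusted p = 0.27 with an estimated correlation; 0 members passed with p-values adjusted over the list alone. With the haemoglobin share in the model the mean log2 fold was 0.23.

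Red blood cell genes were higher as a group with injured fathers by camera. Haemoglobin genes took 0.215% ± 0.0971 of the counts with injured fathers and 0.113% ± 0.0387 with uninjured fathers (SD, n = 4; exact permutation p = 0.057, adjusted p = 0.34 over 6 measures), and the difference of 0.102 points was 0.0535 without the injured library numbered 4. Of 20 tested erythrocyte genes 17 had a positive log2 fold, with a mean of 0.50. The carbonic anhydrase gene cahz was at 108 ± 37.0 against 59.22 ± 13.3 CPM and blvrb, a biliverdin reductase, at 21.4 ± 7.62 against 11.5 ± 2.57 CPM. TMOD4 was at 4.08 ± 0.389 against 1.93 ± 0.501 CPM, and hbaa1 at 686 ± 431 against 382 ± 109 CPM (log2 fold 0.85). Camera gave an adjusted p of 1.6e-05, and an adjusted p = 0.27 with an estimated correlation; 3 members passed with p-values adjusted over the list alone. List scores overlapped, at 5.19 ± 0.246 against 4.75 ± 0.174, with an exact permutation p of 0.057 and an adjusted p of 0.28. The mean log2 fold was 0.31 without the injured library numbered 4, where haemoglobin took 0.360% of the counts, and the call ended with the haemoglobin share in the model (mean log2 fold 0.11). That share includes hbaa1 and other haemoglobin genes and had a higher mean with injured fathers. The fit with it is therefore no independent check of this list.

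Thrombocyte genes had a mean log2 fold of 0.29, with 10 of 11 positive (camera adjusted p = 0.010, and adjusted p = 0.27 with an estimated correlation). Their call ended without the uninjured library numbered 5 (mean 0.25) and without the injured library numbered 7 (0.21), without the low-count filter (0.10) or with a stricter one (0.14), with the haemoglobin share in the model (0.25), and with symbols matched without a final a or b (0.15 over 16 members). None of their members passed with p-values adjusted over the list alone. Ribosomal protein genes had a mean log2 fold of 0.18, with 77 of 80 positive and 0 at an unadjusted p under 0.05 by edgeR (camera adjusted p = 1.6e-05, and adjusted p = 0.63 with an estimated correlation); 0 passed with p-values adjusted over the list alone. Their share of counts was 5.00% ± 0.467 against 4.26% ± 0.482 (SD, n = 4; exact permutation p = 0.14), and the call ended without the injured library numbered 4 (mean log2 fold 0.06), with the haemoglobin share in the model (0.03) and with 1 surrogate variable (0.02). With a gene length offset the mean was 0.12.

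Lists of genes of the heart muscle itself had small mean log2 folds, though single members had larger ones in either direction, such as HCN4 (-1.51) and tpma (0.77). Sarcomere genes had a mean log2 fold of -0.25, with 22 of 25 negative: MYOM1 on chromosome 7, a protein of the M-band, was at 2386 ± 403 against 3310 ± 405 CPM (SD, n = 4), and the troponin C gene tnnc1a at 1923 ± 343 against 2549 ± 328 CPM. Camera gave an adjusted p of 0.010, and an adjusted p = 0.27 with an estimated correlation, and the call ended without the injured library numbered 7 (mean -0.27); 0 members passed with p-values adjusted over the list alone. The calcium handling and conduction list was not called (mean log2 fold -0.27, camera adjusted p 0.13), though HCN4, the pacemaker channel gene, was at 2.25 ± 1.14 against 6.34 ± 1.41 CPM, with an edgeR p of 0.0022 and an adjusted p of 0.43 over all genes. With symbols matched without a final a or b, camera called that list (mean -0.30 over 19 members), and its mean was -0.15 with the haemoglobin share or 1 surrogate variable in the model. With p-values adjusted over the list alone, HCN4 was the 1 member of that list that passed. The cardiac genes MYL7 (a myosin light chain) and nppa (a natriuretic peptide) had log2 folds of -0.10 and 0.08, and nppb, a natriuretic peptide gene of the strained heart, -0.27 with an SE of 0.58 (0.46 without the uninjured library numbered 5). Heart stress and injury genes were not called (mean log2 fold -0.19, camera adjusted p 0.17).

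Further stress and rhythm lists were lower by camera. Heat shock and unfolded protein genes had a mean log2 fold of -0.23 with 28 of 33 negative (camera adjusted p = 0.0078, and adjusted p = 0.47 with an estimated correlation), led by the small heat shock protein gene hspb6 at 436 ± 179 against 838 ± 287 CPM (SD, n = 4) and its partner BAG3 at 72.7 ± 30.8 against 161 ± 65.1 CPM. Hypoxia response genes had a mean of -0.27 with 20 of 26 negative (camera adjusted p = 0.039, and adjusted p = 0.27 with an estimated correlation), among them the glucose transporter gene SLC2A1 on chromosome 6 (-0.56) and EPAS1 on chromosome 12 (-0.59). Circadian clock genes had a mean of -0.25 with 20 of 33 negative (camera adjusted p = 0.042, and adjusted p = 0.42 with an estimated correlation); tefb (-0.81) and BHLHE41 (-1.34) were lower while nr1d4b (1.98) was higher. In these lists 0 members passed with p-values adjusted over the list alone. The heat shock call ended without the uninjured library numbered 5 (mean -0.13) or the injured one numbered 2 (-0.15), and with the haemoglobin share in the model (0.002). Its mean was -0.38 without the injured one numbered 7 and -0.14 with library sizes alone. The hypoxia call ended without the uninjured library numbered 3 (-0.21) or 5 (-0.27), or the injured one numbered 1 (-0.20) or 2 (-0.23), and without the members shared with other lists (-0.17 over 15 members); the mean was -0.41 with the haemoglobin share in the model. The clock call ended without the uninjured library numbered 3 (-0.16), 4 (-0.06) or 5 (-0.25), or the injured one numbered 1 (-0.25) or 4 (-0.17), and also without members of other lists (-0.21), with RLE factors (-0.26), with the haemoglobin share (-0.16) or 1 surrogate variable (-0.02) in the model, and without haemoglobin, mitochondrial and ribosomal protein genes (-0.26). With library sizes alone its mean was -0.16.

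Markers of other leukocytes were not called by camera: neutrophil genes had a mean log2 fold of 0.54 (adjusted p 0.072), lymphocyte genes 0.20 (0.085) and macrophage genes 0.21 (0.10). Without the low-count filter camera called all 3 lists, with means of 0.92 over 16, 0.40 over 35 and 0.41 over 33 members. With a stricter filter it called macrophage genes (0.31) but not neutrophil (0.28) or lymphocyte genes (0.13), and it called lymphocyte genes with 1 surrogate variable (0.25). With the haemoglobin share in the model neutrophil genes had a mean of 0.06, where the camera direction turned to lower, and macrophage genes 0.08. The neutrophil mean was 0.33 without the injured library numbered 4 and 0.35 without the one numbered 1. Leaving out 1 library brought the neutrophil list past the threshold in 4 cases (uninjured 1 and 3, injured 2 and 7; means 0.56, 0.71, 0.64 and 0.68), the lymphocyte list in 2 (injured 2 and 4; 0.21 and 0.22) and the macrophage list in 2 (uninjured 3 and injured 2; 0.35 and 0.33). With p-values adjusted over the list alone, S1PR4 (log2 fold 1.91) passed among neutrophil genes and lgals9l1 among macrophage genes. Of single macrophage genes, marco, a scavenger receptor, was at 12.2 ± 3.35 against 7.03 ± 0.466 CPM (SD, n = 4) and csf1rb at 0.579 ± 0.138 against 1.304 ± 0.746 CPM, with adjusted p of 0.52 and 0.64 over all genes. Over all lists tested, camera called 12 of 33 with the preset correlation, 7 higher and 5 lower, and 0 with an estimated correlation, where 5 had an unadjusted p under 0.05; fry called 0 in 1 direction, where 9 had an unadjusted p under 0.05. The mixed fry test, which asks whether members differ in either direction, called 2 lists, interferon response and inflammatory genes, each with an adjusted p of 0.045.

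The other lists were not called by camera in the main analysis. Mean log2 folds were 0.12 for proteasome genes (adjusted p 0.086), 0.24 for immediate early genes (0.25), 0.18 for nerve (0.35), 0.04 for nuclear-encoded OXPHOS subunits (0.51) and 0.08 for atrium markers (0.80). They were -0.13 for glycolysis (0.10), -0.24 for liver proteins (0.26), -0.14 for chromatin and DNA methylation (0.28), -0.13 for fatty acid use (0.29) and -0.28 for complement (0.29). They were -0.09 for extracellular matrix (0.29), -0.18 for skeletal muscle (0.30), -0.09 for smooth muscle (0.47), -0.05 for epicardium and fibroblasts (0.53), -0.08 for endothelium (0.55) and -0.03 for mitochondrially encoded mRNAs (0.56). Several passed the threshold under another setting. With the haemoglobin share in the model camera called 6 of them lower: immediate early genes (-0.61), liver proteins (-0.50), mitochondrially encoded mRNAs (-0.28), fatty acid use (-0.21), nuclear-encoded OXPHOS subunits (-0.19) and epicardium and fibroblasts (-0.15). With 1 surrogate variable it called complement (-0.41), liver proteins (-0.39), mitochondrially encoded mRNAs (-0.17), glycolysis (-0.16), heart stress and injury genes (-0.11) and nuclear-encoded OXPHOS subunits (-0.08) lower, and the same 6 without both libraries numbered 4. It called proteasome genes higher with library sizes alone (0.20) and glycolysis lower without the low-count filter (-0.17). With 1 library left out, immediate early genes were called higher in 4 cases (uninjured 3 and 4, injured 1 and 2; means 0.39, 0.47, 0.44 and 0.41) and proteasome genes in 3 (uninjured 5, injured 1 and 2; 0.21, 0.15 and 0.16). Glycolysis was called lower in 2 cases (uninjured 4 and injured 4; -0.14 and -0.17), complement without the uninjured library numbered 4 (-0.40), and mitochondrially encoded mRNAs (-0.18) and nuclear-encoded OXPHOS subunits (-0.09) without the injured one numbered 4. Among the epicardium and fibroblast genes, podxl, of a cell surface sialomucin, was at 484 ± 38.8 against 696 ± 86.7 CPM (SD, n = 4). The gonad and the pancreas and gut lists had 3 and 2 tested members and were not tested.

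**Figure D3:**
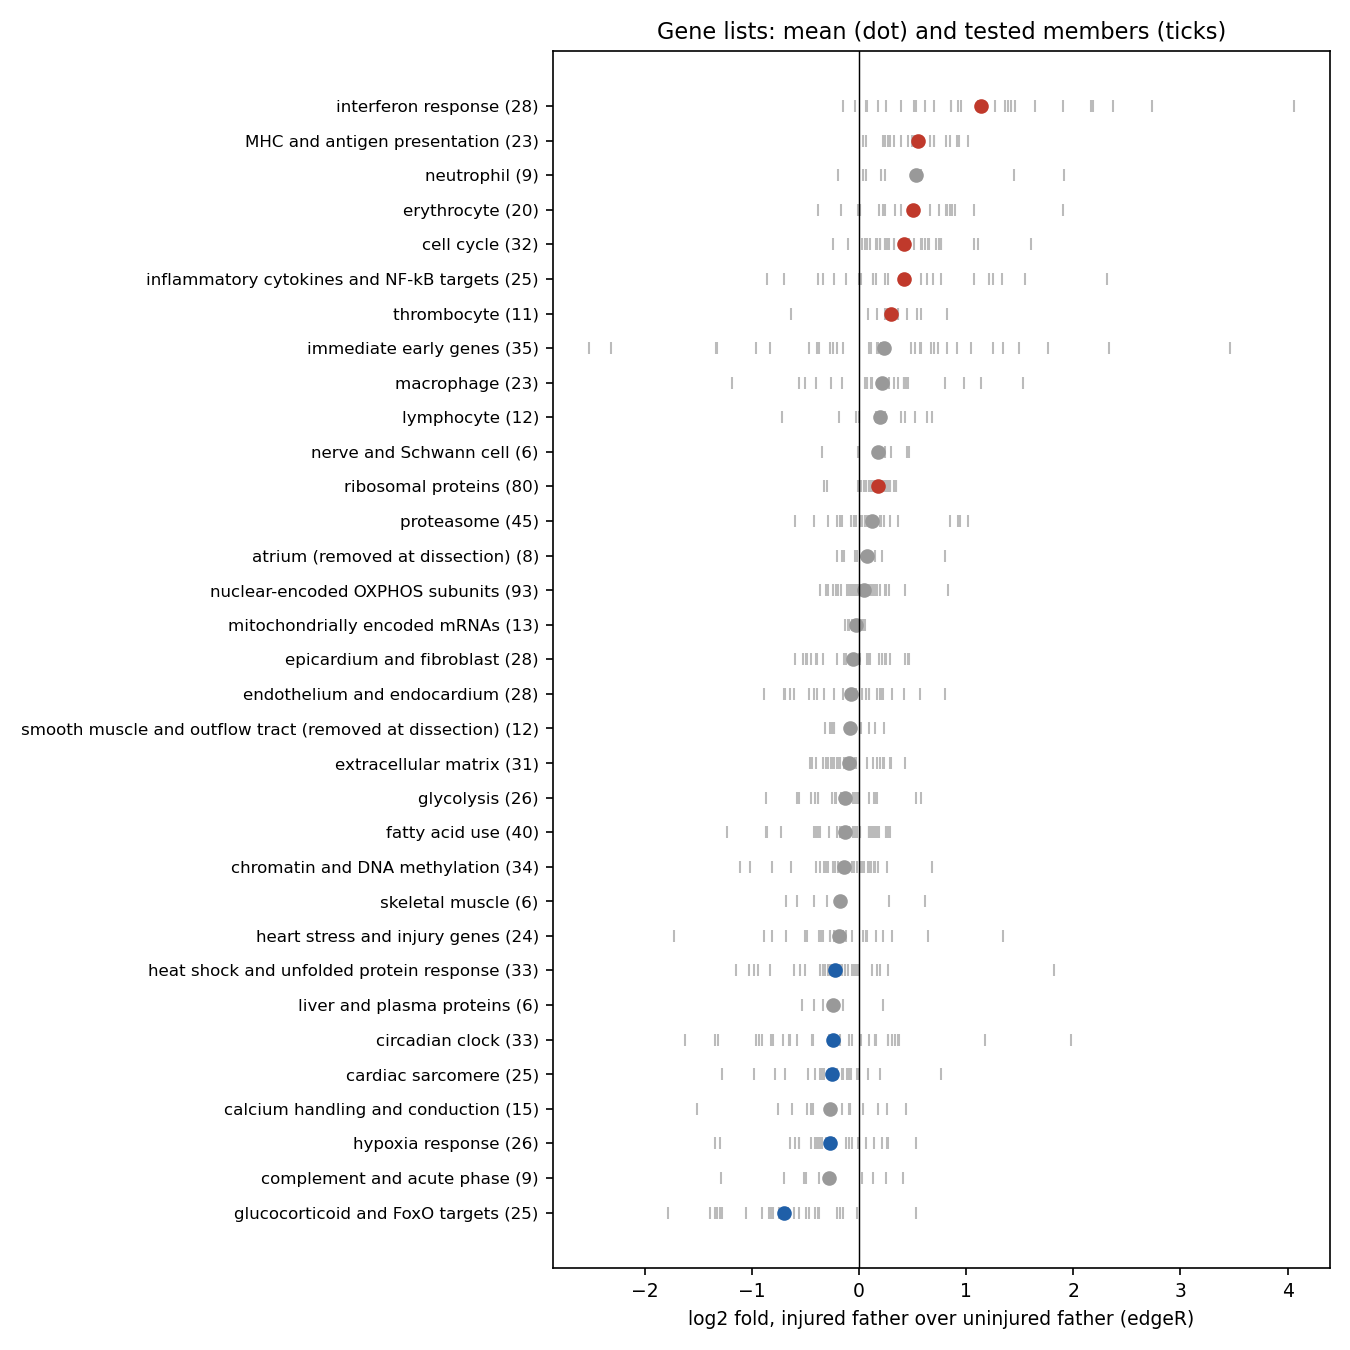
Log2 fold (injured over uninjured father, edgeR) of the tested members of 33 gene lists (grey ticks) and their mean (dot); the number of tested members stands in parentheses. Red dots are the 7 lists higher and blue dots the 5 lower by camera with the preset correlation, grey dots the others; interferon response has the highest mean (1.14) and glucocorticoid and FoxO targets the lowest (-0.70).

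**Figure D4:**
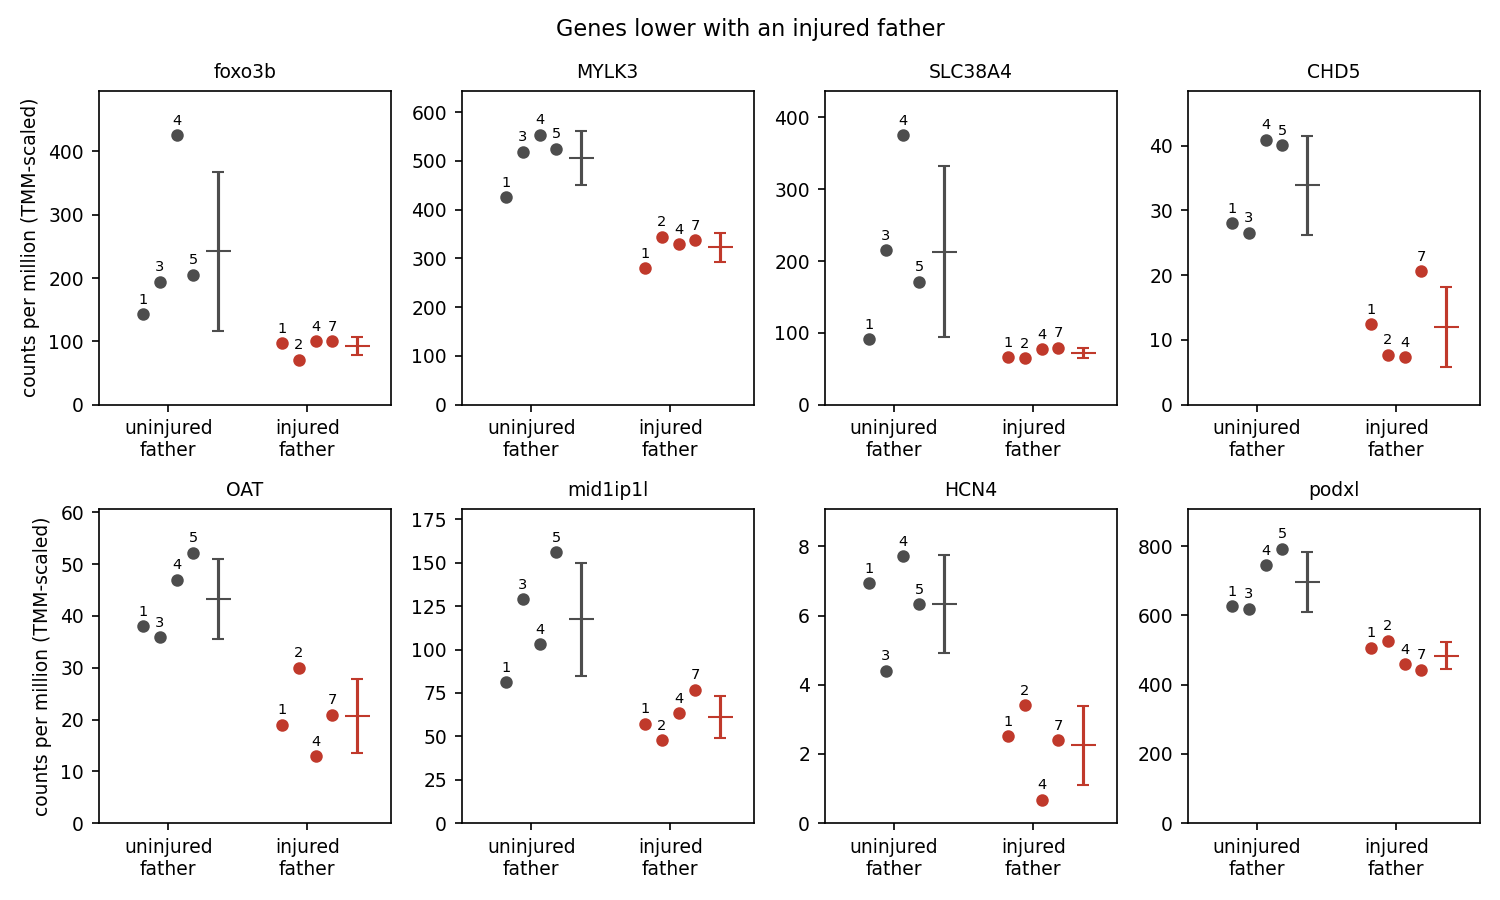
CPM (TMM-scaled, linear axes from 0) of 8 genes that were lower with injured fathers, per library, with library numbers at the points and bars for mean and SD (n = 4). In each panel the 4 libraries of injured fathers lie below the 4 of uninjured fathers; the uninjured library numbered 4 is highest for foxo3b, MYLK3, SLC38A4, CHD5 and HCN4.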

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

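The tests of leukocyte markers (with and without the low-count filter), of the interferon members' chromosomes, of the immediate early score, and of the count of genes that edgeR called in other splits were chosen after the result was seen. In 236 groups of 4 libraries, 16 had 1 library whose gap to the nearest other, over the group's range, was above Dixon's 95% critical value, where chance gives about 12.

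Of these 16 values, 5 were the injured library numbered 7. Its interferon score was 4.04 (the other 3 injured-father libraries 3.091 to 3.237), RSAD2 66.37 CPM (15.27 to 18.36), ifi27.3 48.86 CPM (15.6 to 17.52), PSMB8 35.43 CPM (10.44 to 14.41) and hspb6 705.1 CPM (343.1 to 352.7). The injured library numbered 4 stood apart with a haemoglobin share of 0.36% (0.1554 to 0.1728), PTGS2 at 23.89 CPM (3.32 to 5.38) and blvrb at 32.77 CPM (16.92 to 18.97). The other injured-father values were foxo3b at 70.86 CPM in library 2 (97.25 to 100) and HSPB8 at 3.32 CPM in library 1 (4.93 to 5.08).

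Among uninjured fathers, library 3 stood apart with a haemoglobin share of 0.1705% (0.09004 to 0.101) and cahz at 78.98 CPM (50.36 to 54.96). Library 4 did so with an inflammatory score of 2.498 (2.641 to 2.656), srgn at 43.19 CPM (53.62 to 54.73) and usp2b at 45.57 CPM (16.79 to 21.16), and library 5 with nppb at 160.1 CPM (40.8 to 45.69).

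Higher interferon genes: 1 of the 35 splits of the 8 libraries, the real one and the smallest number the design can give, had a mean log2 fold as far from 0 (real 1.14, highest other 0.90), which argues against chance for this list taken alone; with the list score's exact permutation p at 0.28 after adjustment over 33 lists, chance stays open over all lists. More leukocytes of the 3 types together are argued against as the whole cause in these 8 libraries, since the median log2 fold of 44 macrophage, neutrophil and lymphocyte markers was 0.2427 (bootstrap 95% interval 0.093 to 0.419) and that of the 28 interferon genes 0.94 (0.571 to 1.41). The bootstrap intervals, here and without the low-count filter, resample genes and not libraries, so they do not measure the spread between pools. Without the low-count filter, where camera called all 3 leukocyte lists, the medians were 0.34 (0.132 to 0.453) over 84 markers and 0.99 (0.656 to 1.48) over 36 interferon genes. A pooled median cannot speak to a rise of 1 leukocyte type. The 9 tested neutrophil genes had a mean of 0.54 and a median of 0.24, and the mean was 0.92 over 16 members without the filter. Parental variants in 1 linked block that act only on the members lying there are argued against, since the members' mean was above 0 on 15 of 16 chromosomes. That spread cannot speak to a parental variant that acts on genes of other chromosomes. What stays open, untested, is the father's injury, such a variant, and a rise of 1 leukocyte type. So does any difference between the tanks, clutches or health of the 2 groups, an infection included, which the labels do not separate from the father's injury.

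Lower glucocorticoid and FoxO targets: chance was not excluded, since 11 of the 35 splits gave a mean as far from 0 (real 0.70 below 0, highest other 1.04). The state of the fish at sampling (clock or feeding) cannot be told apart from the father's injury. Deviations of the list score from the group mean went with those of the clock score (r = 0.8554, exact permutation p = 0.15 over 8 libraries, and r = 0.58 without the 2 farthest). That relation cannot decide, since the clock score averages members that went both ways (20 of 33 negative). Both full scores also followed the first principal component (r = -0.86 for the clock list, -0.61 for this list), which did not separate the groups. A response to handling (immediate early genes) stays open too, though the values lean against it: with the immediate early score in the model the score difference was -0.6465 (SE 0.30, 95% interval -1.41 to 0.12), and -0.53 (SE 0.45) without it, in a score that leaves out members shared with the clock list (-0.59 with them). Within groups the 2 scores went together (r = 0.80, exact permutation p = 0.0017, adjusted p = 0.0069 over 4 relations), while the immediate early score, taken without genes of the FoxO list, was 0.17 higher with injured fathers (0.13 with them), the direction opposite to the list's, though camera called immediate early genes lower with the haemoglobin share in the model. The mean log2 fold of the list was -0.71 with that score in the model. The interval of the score difference holds 0 with the immediate early score in the model, but also without it (95% interval -1.64 to 0.58). The difference is thus not set apart from 0 either way, so the fit cannot decide on handling. The father's injury stays open, untested.

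Higher erythrocyte genes: 1 of the 35 splits, the real one, gave a mean as far from 0 (real 0.50, highest other 0.47). The margin is slim, the list score had an exact permutation p of 0.057 (adjusted p = 0.28) and the mean was 0.31 without the injured library numbered 4, so chance stays open. More blood left in the ventricle may account for it: deviations of the haemoglobin share from the group mean went with those of the other erythrocyte genes (r = 0.9336, exact permutation p = 0.028, adjusted p = 0.056 over 4 relations). That relation rests on 2 libraries, without which r was 0.05, and the median log2 fold was 0.84 for 6 haemoglobin genes and 0.37 for 18 other erythrocyte genes. The incision made to let red blood cells out was the same in both groups per the labels, and the father's injury stays open, untested.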

How the results depend on the processing

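Leaving out both libraries numbered 4, limma voom without quality weights, and matching symbols without a final a or b were chosen after seeing the data. EdgeR called 0 genes with RLE, upper-quartile or library-size scaling, other filters, a minimum fold, an adjusted p under 0.1, a length offset, a haemoglobin or surrogate variable covariate and each library left out, with 423 to 1381 genes at an unadjusted p under 0.05; limma voom also called 0 (1150 with and 947 without weights). DESeq2 called 57 (44 higher, 13 lower), 54 of them at an unadjusted p under 0.05 in edgeR; the cause was not tested. The 2 groups share the numbers 1 and 4, and deviations from the group mean correlated at 0.21 and -0.34 for these, so the numbers were not taken as pairs. With the number as a block, only the libraries numbered 1 and 4 inform the difference between the groups, and the remaining libraries add nothing to it. In that fit edgeR called 20 (11 higher, 9 lower), 4 of them also called by DESeq2. There camera called 13 lists, 8 of the 12 (not sarcomere, thrombocyte, heat shock and hypoxia) and 5 others, neutrophil (0.97), macrophage (0.41), nuclear-encoded OXPHOS (0.23), proteasome (0.24) and chromatin (-0.37) genes. Camera called 9 to 17 lists under other settings, 9 to 15 of these with 1 library left out, but 0 with an estimated correlation and 0 by fry; the correlation between members, 0.77 for ribosomal proteins, enters only there. Interferon, MHC, cell cycle and glucocorticoid and FoxO lists kept their call in 23 of 25 alternatives each, the exceptions being estimated correlation and fry.

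With the haemoglobin share as a covariate 6 of the 12 lists kept their call, and the ribosomal, erythrocyte, inflammatory, heat shock, thrombocyte and clock lists lost it, while 6 others gained one. There the camera direction, not the mean, turned for the neutrophil list (0.0553), the mean, not the direction, for heat shock (0.0024), and the log2 fold for hbaa1 (-0.3175), nppa (-0.1822), nppb (0.3592), rgs18 (-0.0235) and srgn (-0.0231). Others that turned were kcnh6a (0.1197 with 1 surrogate variable, 0.0072 without both libraries numbered 4), the camera direction of the ribosomal list without both (mean 0.0015) and nppb without the uninjured library numbered 5 (0.4627; from -0.9 over the libraries left out). Because hbaa1 is part of the haemoglobin share, its turn there says nothing by itself. The mean share was also higher with injured fathers (0.215% against 0.113%), so that fit can take up part of the difference between the groups. The causes of the other turns were not tested. GC content was not run, for want of a genome sequence. Where 1 library was left out, 3 stood against 4. At 9.12 to 17.2 counts per CPM, genes under 1 CPM rest on few counts, and 24.6% of 2-fold changes were recovered on simulated data.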

Other observations

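The families below and the comparison of MHC members by chromosome were chosen after the result was seen. Grouped by the stem of the symbol, 444 families had at least 5 tested members, and camera called 14 with the preset correlation (11 higher, 3 lower) and 0 with an estimated correlation. The highest by p was ftr, the fish-specific TRIM genes, with 23 of 25 positive, 10 members at an edgeR p under 0.05, and a mean log2 fold of 0.76 (adjusted p = 3.6e-09, and adjusted p = 0.92 with an estimated correlation). All 8 tested ifi27 genes, on chromosome 13, were positive, with a mean of 1.38 (adjusted p = 8.7e-08, and adjusted p = 0.99 with an estimated correlation); neither family is in the interferon list. Interleukin-named genes (il) had 10 of 11 positive and a mean of 0.47 (adjusted p = 0.0054, and adjusted p = 0.92 with an estimated correlation). Lower were chd, the chromatin remodellers of the CHD5 family, with 0 of 11 positive and a mean of -0.45 (adjusted p = 0.019, and adjusted p = 0.99 with an estimated correlation), ehd (mean -0.54, 0 of 5, adjusted p = 0.038) and map3k (mean -0.36, 0 of 13, adjusted p = 0.043), both with an adjusted p = 0.99 with an estimated correlation.

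DESeq2 also called genes outside the lists and the rule for named genes, chosen here after their values were seen: herc56.3 (log2 fold 2.68), herc56.2 (2.15), ifi44a1 (2.06), helz2b (1.25), ftr91 (2.47), the endothelial adhesion gene sele (1.66) and the galectin gene lgals9l3 (1.02) were higher, and LMBR1L (-1.82) was lower. Reads that map to several copies were not counted, so values of single herc56, ftr and galectin genes are uncertain.

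Chance was not excluded for the counts over all genes. Of the 35 splits of the 8 libraries, 8 gave as many genes at an unadjusted edgeR p under 0.05 (real 971, highest other 2245), 5 as many genes by DESeq2 (real 57, highest other 342), and 4 as many lists by camera (real 12, highest other 12). In the other splits camera called 0 to 12 lists, and 12 also where uninjured libraries 1 and 5 stood with injured libraries 1 and 4. Such calls with the preset correlation therefore do not by themselves mark the father's group. With 0 genes called by edgeR in the real split, all 35 necessarily gave as many (highest other 11), so that count, a test chosen after the result was seen, says nothing of chance. Splits with several times the real count point to a structure of the libraries other than the father's group. The first principal component (34.3% of the variance) had the uninjured library numbered 4 at -65.6 and the injured one numbered 4 at 53.5, and did not separate the groups (exact permutation p = 0.2).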
